A study of Mus musculus with 6 samples.

How the data were processed

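RNA from the lungs of mice was measured on 6 Affymetrix 3' expression arrays, 3 labelled as control and 3 labelled as carrying a deletion of Pten. Per the labels, total RNA was extracted with Trizol and biotinylated cRNA was prepared by the array maker's standard protocol. The authors deposited 1 value per probe set and array, a linear signal intensity made with MAS5, per the submitters' processing notes; the software version, any masking and the detection calls are not given in the sources used here. MAS5 is a method that combines the probe pairs of a probe set into 1 signal per array. The deposited intensities were all above 0, and their mean without the top and bottom 2% of probe sets was 1500 on each array, so that overall brightness had already been equalised. Such scaling removes differences in overall brightness, but it does not remove differences in RNA integrity or in tissue composition between arrays.

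The table held 45101 probe sets, of which 64 were control probe sets and were used only to describe the arrays. Gene names came from the platform annotation of 2016, and symbols were checked through the Entrez identifier against the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols; 204 probe sets had no entry in that table and kept the annotation's symbol. That assembly was used for names only, since the sources used here name no genome build for the array data, and no coordinates are given. In total 34958 probe sets had 1 gene symbol, 932 had several and were not named, and 9160 probe sets other than controls were unnamed here. The annotation used named 0 probe sets for Pten, so the targeted gene was not analysed here, and the labels were not checked against its transcript.

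Signals were transformed as log2(signal + 59.07), where the pseudocount was the 20th percentile of all values in the table. No further normalization was applied. Differences are therefore on the log2(signal + pseudocount) scale, which understates the change of dim genes. Probe sets were kept where the mean log2 value over the 6 arrays was at or above the 40th percentile (7.98), which left 27022 probe sets. For the gene-level analysis each of the 18193 named genes was represented by its probe set with the highest mean over the 6 arrays, chosen without regard to group, and 12826 genes passed the same filter. PTEN deletion was compared with control in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with a mean-variance trend), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used, since the labels name none. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. Each group held arrays of both sex patterns, so the 3 arrays of a group were not all repeats of 1 animal.

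Before the data were examined, 34 gene lists (677 different genes, 52 of them with no named probe set here) were fixed for signalling pathways, stress programmes and the cell types a lung sample could hold. The fit, the rule for named genes and the first set of alternatives were fixed at the same time. Each list with at least 5 tested members was tested with camera in limma, which compares a list with all other tested genes, at a preset correlation between genes of 0.01. Camera with the correlation estimated from the data and fry were run as alternatives. The 9 genes that belong to more than 1 list count in each. The genes named were to be those past the threshold with the largest changes. With fewer than 10 genes past it, the rule took the 10 genes with the smallest p whose groups did not overlap, reported as not passing, and up to 4 members with the smallest p from each list described. Clone-based and predicted gene names were passed over.

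The arrays were compared by the ratio of 3' to 5' signal of the control probe sets for beta-actin and Gapdh, by spiked-in control transcripts, by Spearman correlation and by principal components. The replicate numbers were checked for pairing through the correlation of deviations from the group means. Alternatives covered quantile normalization, median centring, 2 other pseudocounts, 2 other filters, 3 other variance models, the mean of a gene's probe sets, the replicate number as a block, other thresholds, and leaving out each array in turn. A block for the sex read from Xist and the Y-linked genes, an estimated correlation with control replicate 3 left out, and the counts at unadjusted p under the alternatives, were added after the data were seen. The fit was tested on simulated values with the measured spread of the 6 arrays, over 12826 genes of which 67, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold. It recovered 2.99% of genes changed by 1.5-fold, 38.8% of those changed by 2-fold and 83.3% of those changed by 4-fold, with 4 false calls. With the spread measured without control replicate 3 it recovered 26.9%, 55.2% and 90.9%, with 9 false calls. The simulated genes were independent of each other and had the same spread on all 6 arrays. In the data genes vary together and control replicate 3 stands apart, so these rates may not carry over. Precision is limited by the number of arrays and by the spread that control replicate 3 adds: the median standard error of a gene's log2 difference was 0.22. Figures were drawn with matplotlib 3.10.9.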

Results

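Gene expression was measured in mouse lungs on 6 arrays, 3 from control mice and 3 from mice with a deletion of Pten, the gene for a lipid phosphatase that opposes PI3K signalling. The series is titled as a genome-wide study of Pten deletion in lung epithelial cells. Its labels describe mice with a floxed Pten exon in which doxycycline-induced Cre recombinase acts in the lung epithelium through the SP-C or the CCSP promoter. The labels also mention tumours in mice that carry a Kras allele as well, without saying which driver line or allele each array came from. The tissue is named as lung epithelium in one label and as lungs in another. Sftpc, an alveolar type 2 surfactant gene, had signals between 32780 and 92957 intensity units on the 6 arrays, and Myh6, the cardiac myosin heavy chain, between 13185 and 35055. Median signals per array lay between 337.9 and 386.4 units, against a 20th percentile of 47.7 to 94.8.

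Control replicate 3 stood apart from the other arrays. Its ratio of 3' to 5' signal was 11.0 for beta-actin and 11.5 for Gapdh, against 1.96 to 2.39 and 1.97 to 2.53 on the other 5 arrays. This ratio goes up as RNA is degraded, but no direct measure of RNA integrity was used here. Its signal for the spiked-in transcript BioB was 12488, against 4036 to 5542 elsewhere. Its Spearman correlation with the other arrays was 0.898 to 0.932, while the other 5 correlated at 0.959 to 0.978 with each other. The first principal component, with 60.01% of the variance, placed it at 101.0 and the others between -37.9 and 13.3. Xist, which is expressed from the inactive X chromosome of females, had signals of 19276 on control replicate 2 and 22348 on PTEN-deletion replicate 3, and of 389 to 678 on the other arrays. The Y-linked gene Eif2s3y had the opposite pattern, at 99 and 68 on those 2 arrays and 5597 to 8457 on the others, so that each group held 1 array of the female pattern.

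**Figure D1:**
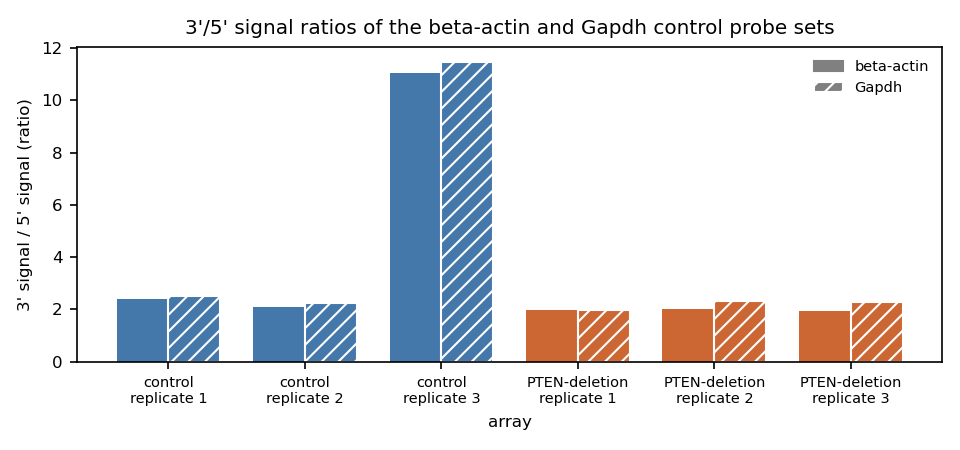
Bars give the ratio of 3' to 5' signal (y axis, no unit) of the beta-actin (plain) and Gapdh (hatched) control probe sets on each of the 6 arrays (x axis), with control arrays in blue and PTEN-deletion arrays in orange. Control replicate 3 reached 11.0 and 11.5, and the other 5 arrays lay between 1.96 and 2.53.

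The arrays were compared to ask which transcripts differ in the lung after Pten deletion. Genes of the unfolded protein response and of the immediate early and heat shock responses had lower signals on the PTEN-deletion arrays. Markers of secretory airway cells, ciliated cells and T and NK cells had higher signals, and endothelial markers, inflammatory cytokine genes and RAS-MAPK output genes had lower ones. These statements rest on gene lists, of which 9 of 32 passed camera at a preset correlation (4 higher, 5 lower) and 0 passed with an estimated correlation. Other divisions of the same 6 arrays into 3 and 3 gave 2 to 11 lists at the preset correlation. No single gene passed: limma found 0 of 12826 genes and 0 of 27022 probe sets at an adjusted p under 0.05, with smallest adjusted p of 0.443 and 0.48. At an unadjusted p under 0.05 there were 1445 genes, 776 higher and 669 lower, where 641 would come by chance. That count was unstable when an array was left out, an alternative for it chosen after the data were seen: it was 503 without PTEN-deletion replicate 3, below the number by chance, and 3039 without control replicate 2. Median centring of the arrays turned that split to 569 higher and 913 lower, so the balance of directions depends on the scaling. The arrays of the groups did not overlap for 2469 genes (19.3%, against 10% by chance). Genes vary together, so a count can lie far from its chance value without a difference between groups. The other divisions of the 6 arrays gave 54 to 1085 genes at unadjusted p under 0.05.

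The named genes with the smallest p and no overlap between groups had adjusted p = 0.443 each in limma and are given as not passing. Differences are log2 values, PTEN deletion minus control, ± the standard error of the fit, with n = 3 arrays per group. Cdkn1a (probe set 1424638_at), which encodes the cyclin-dependent kinase inhibitor p21, differed by -1.46 ± 0.27, with signals of 14920 to 26159 on the control arrays and 4841 to 8256 on the PTEN-deletion arrays. Per3 (1421087_at), a gene of the circadian clock, differed by 1.07 ± 0.18, with signals of 3056 to 4609 against 8141 to 8680. Ifit3 (1449025_at), an interferon-induced gene, differed by 1.11 ± 0.19. Adh7 (1421058_at), an alcohol and retinol dehydrogenase of epithelia, differed by 1.74 ± 0.34, and Fbp2 (1449088_at), a fructose bisphosphatase known from muscle, by 0.99 ± 0.20. Among genes with lower signals were Il4ra (1421034_a_at), a receptor chain for interleukins 4 and 13, at -0.93 ± 0.18, and Selp (1420558_at), the adhesion molecule P-selectin, at -1.15 ± 0.23. Tmem252 (1437595_at) differed by -1.95 ± 0.33, Cacna2d4 (1457703_at), a calcium channel subunit, by -1.45 ± 0.29, and Exoc3l2 (1428867_at) by -1.21 ± 0.22. The rule took only genes whose groups did not overlap, so leaving out 1 array could not turn the direction of these 10 genes. Without control replicate 3 the differences were, for example, -1.23 for Cdkn1a and 0.88 for Per3. Averaging the probe sets of each gene gave smaller differences for Exoc3l2 (-0.45) and Il4ra (-0.58).

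**Figure D2:**
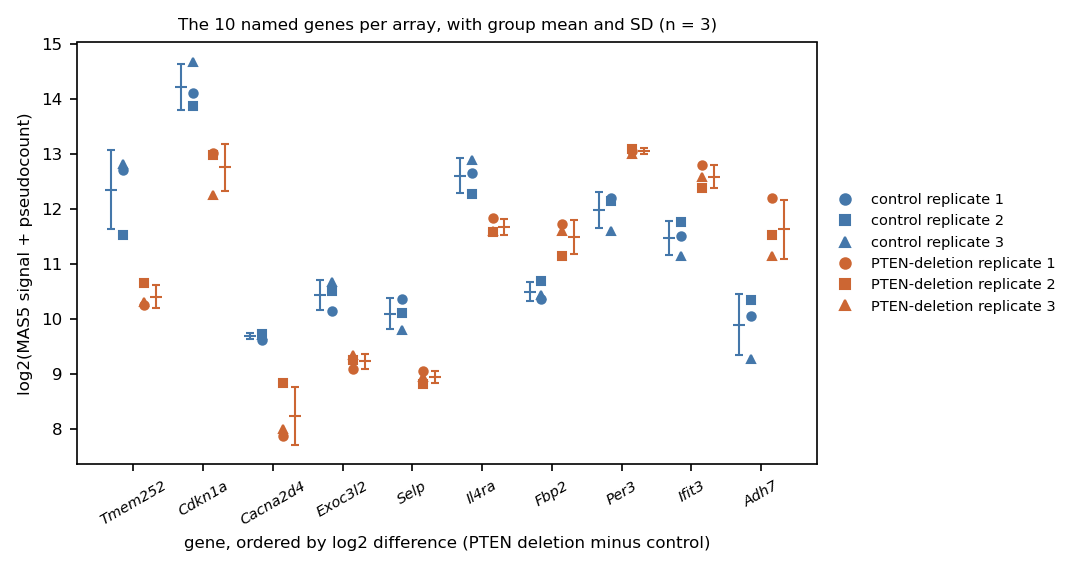
Points give log2(signal + pseudocount) (y axis) of the 10 named genes (x axis) on each array, with control arrays in blue and PTEN-deletion arrays in orange, and bars give the mean ± SD of each group (n = 3). For each gene the 3 arrays of one group lie above the 3 of the other, as for Tmem252, at -1.95 on the log2 scale, and Adh7, at 1.74.

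All 20 tested genes of the unfolded protein response, the programme that adjusts protein folding in the endoplasmic reticulum, had lower signals on the PTEN-deletion arrays, with a median log2 difference of -0.49. The list passed camera at adjusted p = 1.02e-08, and did not pass at adjusted p = 0.878 with an estimated correlation. Of these genes 5 passed when adjusted over the list alone, and 0 over all genes. They were Manf at -0.74 ± 0.17, Creld2 at -0.92 ± 0.24, Hyou1 at -0.92 ± 0.27, Sdf2l1 at -0.79 ± 0.23 and, named after its value was seen, the transcription factor gene Xbp1 at -0.58 ± 0.18. Averaged over the list, the PTEN-deletion arrays lay between -0.44 and -0.55 relative to the control mean, control replicates 1 and 3 at 0.09 and 0.25, and control replicate 2 at -0.34. Without control replicate 3, the array with the high 3'/5' ratios, the median was -0.33 and all 20 genes were lower (adjusted p = 7.14e-09).

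Of the 21 tested immediate early and heat shock genes, 19 were lower, with a median of -0.50 (camera adjusted p = 4.15e-07, and adjusted p = 0.878 with an estimated correlation). No member passed when adjusted over the list alone. Fos, an immediate early transcription factor, differed by -0.68 ± 0.23 and Hspb1, a small heat shock protein, by -1.18 ± 0.38. The Hsp70 genes Hspa1b and Hspa1a differed by -0.95 ± 0.28 and -1.28 ± 0.39, and are near-identical copies that the array may not separate. The median of the list was -0.32 without control replicate 3, with 20 of 21 genes lower (adjusted p = 8.93e-08), and Hspb1 differed by -0.78 there.

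Markers of club cells, the secretory cells of the small airways, were higher for 12 of 17 tested genes, with a median of 0.44 (adjusted p = 0.0118, and adjusted p = 0.878 with an estimated correlation). Reg3g, an antimicrobial lectin, differed by 2.96 ± 0.73, Sult1d1, a sulfotransferase, by 1.33 ± 0.40, Cldn10 by 0.93 ± 0.28 and Cckar by 0.78 ± 0.25. The other 5 genes of the list were lower. Scgb1a1, which encodes CCSP and was not named by the rule, differed by -0.38 ± 0.36. Its signals overlapped, at 45818 to 120559 on the control arrays and 45514 to 60165 on the PTEN-deletion arrays. Goblet and mucous cell markers were higher for 8 of 10 tested genes, with a median of 0.76 (adjusted p = 0.0304, and adjusted p = 0.878 with an estimated correlation). Adjusted over the list alone, 2 goblet genes and 0 club genes passed. The 2 were Itln1 at 2.85 ± 0.71 and Agr2 at 2.12 ± 0.58, and the mucin gene Muc5b differed by 1.28 ± 0.44 and Creb3l1 by -0.71 ± 0.25. Signals of Itln1 were 3468 and 4060 on PTEN-deletion replicates 1 and 3, 444 on replicate 2 and 175 to 250 on the control arrays. Without control replicate 3 the medians were 0.36 for the club list, with 17 of 17 genes higher (adjusted p = 7.10e-05), and 0.42 for the goblet list, whose call was lost (adjusted p = 0.0828), and Muc5b differed by 0.75. Leaving out control replicate 2 ended both calls (median 0.41 and adjusted p = 0.247 for club, median 0.93 and adjusted p = 0.135 for goblet), and leaving out PTEN-deletion replicate 1 ended the goblet call (median 0.59, adjusted p = 0.102). Array quality weights, whose estimate gave a convergence warning, ended both calls as well (median 0.27 and adjusted p = 0.0787 for club, median 0.56 and adjusted p = 0.343 for goblet), and testing without a filter ended the goblet call (median 0.62, adjusted p = 0.059). The club median was 0.68 without PTEN-deletion replicate 2 (adjusted p = 0.000144).

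Ciliated cell markers were higher for 20 of 23 tested genes, with a median of 0.29 (adjusted p = 0.0116, and adjusted p = 0.911 with an estimated correlation). Adjusted over the list alone, 0 passed. Traf3ip1 differed by 0.43 ± 0.14, Dynlrb2, a dynein light chain gene, by 0.62 ± 0.22, Mlf1 by 0.64 ± 0.24 and Ccdc113 by 0.69 ± 0.29. The groups overlapped in the mean of the list relative to the control mean, with control replicate 2 at 0.31 and PTEN-deletion replicates 1, 2 and 3 at 0.54, 0.02 and 0.34. The call was lost without control replicate 3 (median 0.11, adjusted p = 0.0558), where Mlf1 differed by 0.38, and without PTEN-deletion replicate 1 (median 0.12, adjusted p = 0.259). The median was 0.46 without PTEN-deletion replicate 2 (adjusted p = 6.36e-05).

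T and NK cell markers were higher for 15 of 16 tested genes, with a median of 0.68 (adjusted p = 0.00236, and adjusted p = 0.911 with an estimated correlation). None passed when adjusted over the list alone. Klrd1, an NK cell receptor chain, differed by 0.82 ± 0.22, the T cell receptor components Cd3d and Cd3g by 0.95 ± 0.41 and 1.02 ± 0.44, and the interleukin 7 receptor gene Il7r by 0.66 ± 0.33. Averaged over the list, PTEN-deletion replicates 2 and 3 lay at 1.01 and 0.88 relative to the control mean, PTEN-deletion replicate 1 at -0.02 and control replicate 2 at 0.54. The B and plasma cell list, which did not pass, was likewise highest on PTEN-deletion replicates 2 and 3 and control replicate 2 (0.89, 0.48 and 0.43) and lower on the other 3 arrays (-0.38 to -0.05). The median was 0.39 without control replicate 3 (adjusted p = 0.02), with Il7r at 0.38, and the call was lost without PTEN-deletion replicate 2 (median 0.47, adjusted p = 0.062).

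Endothelial markers were lower for 16 of 22 tested genes, with a median of -0.29 (adjusted p = 0.00205, and adjusted p = 0.878 with an estimated correlation). Plvap differed by -0.59 ± 0.19, the capillary lipase anchor Gpihbp1 by -0.43 ± 0.15, Egfl7 by -0.37 ± 0.15 and the receptor gene Tie1 by -0.47 ± 0.20. Inflammatory cytokines and NF-kB targets were lower for 12 of 15 tested genes, with a median of -0.16 (adjusted p = 0.0304, and adjusted p = 0.878 with an estimated correlation). The acute phase gene Saa3 differed by -2.08 ± 0.58 and the chemokine genes Cxcl2 and Cxcl1 by -1.81 ± 0.54 and -1.08 ± 0.43. RAS-MAPK output genes were lower for 11 of 15 tested genes, with a median of -0.18 (adjusted p = 0.0486, and adjusted p = 0.878 with an estimated correlation). The ERK phosphatase gene Dusp6 differed by -0.51 ± 0.15, Spred1, an inhibitor of the pathway, by -0.66 ± 0.26, Phlda1 by -0.61 ± 0.24, and Etv5, a transcription factor gene, by 0.56 ± 0.18. Adjusted over each list alone, 0 genes of these 3 lists passed. None of the 3 separated the groups by its mean per array relative to the control mean. Control replicate 2 lay among the PTEN-deletion arrays for the inflammatory list (-0.38, against -0.37 to -0.50) and for RAS-MAPK (-0.26, against -0.13 to -0.32), and PTEN-deletion replicate 2 among the controls for the endothelial list (-0.04, against -0.09 to 0.10). Without control replicate 3 the medians were -0.20 for the endothelial list (adjusted p = 0.000323), -0.23 for RAS-MAPK output (adjusted p = 0.0473) and -0.11 for the inflammatory list, whose call was lost (adjusted p = 0.0857). On the same 5 arrays Tie1 differed by -0.27, Cxcl2 by -1.19, Cxcl1 by -0.61 and Spred1 by -0.35. The endothelial call was lost without PTEN-deletion replicate 1 (median -0.21, adjusted p = 0.0718). The inflammatory call was lost without control replicate 1 (median -0.09, adjusted p = 0.137), as was the RAS-MAPK call (median -0.07, adjusted p = 0.38). Both were larger without control replicate 2 (median -0.31 and adjusted p = 0.0035 for the inflammatory list, median -0.56 and adjusted p = 0.00606 for RAS-MAPK). Without PTEN-deletion replicate 2 both had adjusted p = 0.062 (medians -0.15 and -0.28), and without PTEN-deletion replicate 1 the RAS-MAPK list had adjusted p = 0.196 (median -0.17). Median centring of the arrays also ended these calls while the medians grew (median -0.26 and adjusted p = 0.0526 for the inflammatory list, median -0.27 and adjusted p = 0.0835 for RAS-MAPK). The RAS-MAPK call, close to the threshold, was also lost without a filter (median -0.30, adjusted p = 0.0677) and, with the median unchanged at -0.18, with eBayes without trend (adjusted p = 0.0543) and with a block for sex, added after the data were seen (adjusted p = 0.0521). A filter at the 60th percentile ended the inflammatory call (median -0.13, adjusted p = 0.0665). Array quality weights kept both calls with larger medians (-0.32 and adjusted p = 0.00672 for the inflammatory list, -0.51 and adjusted p = 0.00448 for RAS-MAPK). The estimate of these weights gave a convergence warning. It put most of the control weight on control replicate 1 (4.48, against 0.47 for control replicate 2), the array without which both calls were lost.

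**Figure D3:**
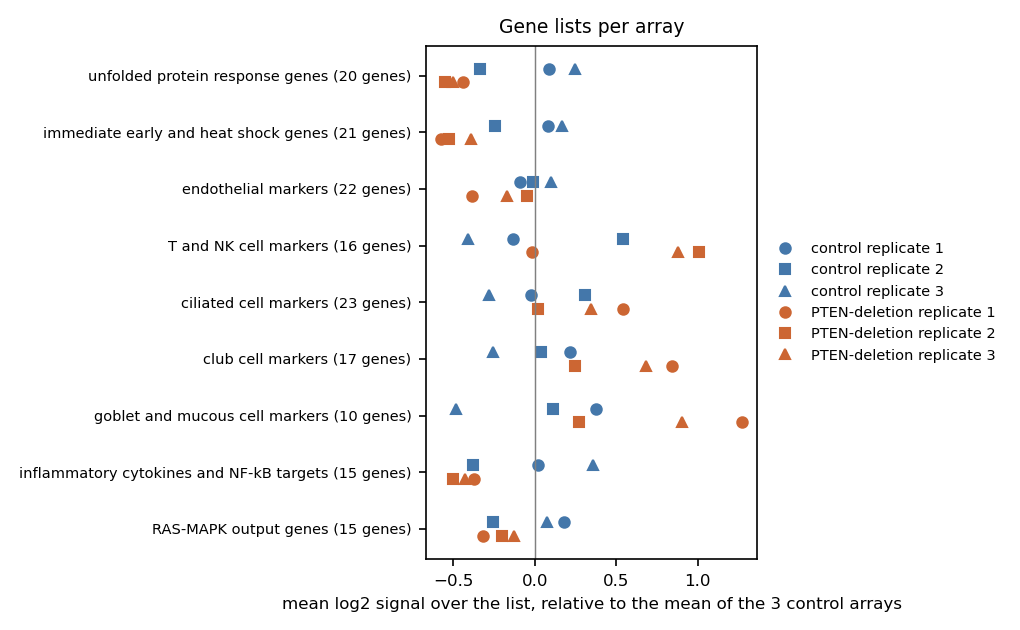
Each point is the mean log2 signal of a gene list on 1 array relative to the mean of the 3 control arrays (x axis), for the 9 lists past camera at the preset correlation (y axis, with the number of tested genes), with control arrays in blue and PTEN-deletion arrays in orange. The PTEN-deletion arrays lie between -0.44 and -0.55 for the unfolded protein response, while for T and NK cells PTEN-deletion replicate 1, at -0.02, lies among the control arrays.

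Lists tied to the deleted gene's pathway, and lists of other cell programmes, did not pass camera. The lists measure transcripts and not the activity of a pathway, and Pten itself was not analysed. The Myh6 signals show that the samples held more than epithelium, so a change limited to epithelial cells could be missed. Among 22 tested components of the PI3K-AKT-mTOR pathway, 10 were higher and 12 lower (adjusted p = 0.996). The regulatory subunit gene Pik3r3 differed by 1.04 ± 0.26 and the translation repressor gene Eif4ebp1 by -0.65 ± 0.17. Of 22 target genes of the FoxO transcription factors, which AKT restrains, 11 were higher and 11 lower (adjusted p = 0.801), with Sesn3 at 0.74 ± 0.18 and Klf2 at -0.78 ± 0.28. Of 26 cell cycle and mitosis genes, 14 were higher and 12 lower (adjusted p = 0.938), with Melk at 0.67 ± 0.22, Kif11 at -1.08 ± 0.42, Bub1 at -0.58 ± 0.26 and Top2a at 0.60 ± 0.27. The p53 target and senescence genes were split 8 to 8 (adjusted p = 0.801), and 1 of them, Cdkn1a, passed when adjusted over the list alone. Epithelial-mesenchymal transition genes were split 12 higher to 11 lower (adjusted p = 0.948), glycolysis and hypoxia genes 9 to 12 (adjusted p = 0.429), NRF2 targets 10 to 10 (adjusted p = 0.952) and cholesterol and fatty acid synthesis genes 9 to 13 (adjusted p = 0.996). The cholesterol median turned from -0.09 to 0.02 with control replicate 3 left out, with 15 genes higher and 7 lower. Interferon-stimulated genes were split 11 to 10 (adjusted p = 0.999), and 1, Ifit3, passed over the list alone. Circadian clock genes were split 9 to 6 (adjusted p = 0.772), and Per3 and Hlf, at 1.34 ± 0.34, passed over the list alone. Lung developmental and progenitor factors were split 15 to 5 (adjusted p = 0.198), with Foxp2 at -0.93 ± 0.27, Etv5 at 0.56 ± 0.18, Hmga2 at -1.18 ± 0.41 (-0.68 without control replicate 3) and Foxa1 at 0.64 ± 0.23. Adjusted over the list alone, 0 genes passed in the other lists of this paragraph.

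The remaining lists, of other cell types, did not pass camera either. Alveolar type 2 markers were higher for 5 and lower for 14 genes (adjusted p = 0.388) and alveolar type 1 markers higher for 10 and lower for 8 (adjusted p = 0.471). B and plasma cell markers were higher for 14 and lower for 2 (adjusted p = 0.0705), with Jchain at 0.64 ± 0.18. Without control replicate 3 the alveolar type 1 list passed (median 0.11, adjusted p = 0.00537), as did the B and plasma cell list (median 0.45, adjusted p = 0.0473), but neither passed there with an estimated correlation (adjusted p = 0.979 and 0.982). Both also passed camera with all 6 arrays after quantile normalization (medians 0.20 and 0.47, adjusted p = 0.00165 and 0.0267). After median centring the B and plasma cell list passed (median 0.31, adjusted p = 0.0244) and the alveolar type 1 list did not (median -0.06, adjusted p = 0.561). Leaving control replicate 3 out turned the alveolar type 2 median from -0.14 to 0.03, with 13 genes higher and 6 lower, the cardiac median from 0.07 to -0.17, with 6 higher and 14 lower, and the mesothelial median from 0.10 to -0.14, with 4 higher and 7 lower (adjusted p = 0.0603). The direction of the alveolar type 2 median also depended on scaling with all 6 arrays, at 0.06 after quantile normalization and -0.24 after median centring. Macrophage markers were split 9 to 8 (adjusted p = 0.693), fibroblast and extracellular matrix genes 6 to 17 (adjusted p = 0.138), smooth muscle markers 5 to 7 (adjusted p = 0.388), mesothelial markers 6 to 5 (adjusted p = 0.59) and basal and squamous markers 9 to 5 (adjusted p = 0.693). Cardiac and striated muscle markers were split 14 to 6 (adjusted p = 0.938), adipocyte markers 6 to 1 (adjusted p = 0.801), neutrophil markers 4 to 9 (adjusted p = 0.169) and sex-linked genes 4 to 3 (adjusted p = 0.801). Median, mean and test differed in sign for the cell cycle, cholesterol, epithelial-mesenchymal, FoxO, interferon, mesothelial, NRF2, p53, PI3K and sex-linked lists. The gastrointestinal and red blood cell lists had 3 tested genes each and were not tested as lists. Adjusted over the list alone, the red blood cell genes Hba-a2, at 0.89 ± 0.25, and Alas2, at -0.75 ± 0.24, passed in opposite directions, and 0 genes passed in the other lists of this paragraph.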

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

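The counts of genes at unadjusted p under the alternatives, the block for sex, and the estimated correlation with control replicate 3 left out were chosen after the data were seen. With array quality weights limma called 2 probe sets and 1136 genes (625 higher, 511 lower) and 4098 genes at unadjusted p under 0.05. The weights were 4.48, 0.47 and 0.19 for control replicates 1, 2 and 3, and 1.01 to 1.86 for the PTEN-deletion arrays. The weighted control values therefore rest mostly on control replicate 1. The estimate of these weights stopped with a convergence warning, so the weighted results are uncertain. The 2 probe sets, named after their values were seen, were that of Gnb4 (1.86 ± 0.17) and the unnamed 1424923_at (-1.99 ± 0.20). An unadjusted p with a 1.5-fold minimum gave 1850 probe sets and 884 genes. Leaving out each array in turn gave 0 to 1 probe sets, 0 to 3 genes and 503 to 3039 genes at unadjusted p, the lowest without PTEN-deletion replicate 3 and the highest without control replicate 2, and 862 without PTEN-deletion replicate 1. The genes, named after their values were seen, were Gas1, Thbs1 and Tmem252 without control replicate 2, Chil1 and Glycam1 without PTEN-deletion replicate 1, and Itln1 without PTEN-deletion replicate 2, and the probe sets were those of Glycam1 and Itln1. Each other alternative at the adjusted threshold gave 0 genes. The lists past the threshold numbered 0 with an estimated correlation, 0 with fry in either form, 0 with both control replicate 3 left out and an estimated correlation, and 8 to 12 of 32 otherwise. The unfolded protein response and the immediate early and heat shock lists passed in each of the other 17 alternatives. The rest lost the call in 1 (endothelial, T and NK), 2 (ciliated, club), 5 (goblet, inflammatory) or 7 (RAS-MAPK) of the 17, with adjusted p of 0.0521 to 0.381 there. The basal and squamous list turned from higher to lower with array quality weights (median -0.45, adjusted p = 0.0325). The cause of these changes was not tested. Over 2476 refits of 139 named genes, 24 changed sign, in 12 genes, and 0 of these reached the threshold.

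No pairing by replicate number was seen: deviations of same-numbered arrays correlated at 0.17, -0.05 and -0.07. Those of differently numbered arrays correlated at -0.14 to 0.19. So few arrays cannot exclude a pairing. With the replicate block 0 genes passed, 1429 had an unadjusted p under 0.05 and 12 lists passed. Centring and quantile normalization moved the median of all genes from 0.04 to -0.06 and 0.02. Robust eBayes has no list test. No probe set was named for Pten in the annotation used, so no value is given for it under any setting. Dim genes limit what can be seen, since a pseudocount near the 20th percentile of signal compresses their differences.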

Other observations

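The tests of RNA quality, of airway share, and of the splits for array weights and for the unfolded protein response were chosen only after the results they measure were seen, and all genes singled out here were too. The bar for the tests of RNA quality and of airway share was revised once with their values in view. Markers of neutrophils parted the arrays across the groups. S100a8 had signals of 28223 to 38213 on control replicates 1 and 3 and PTEN-deletion replicate 1, and of 5861 to 7284 on the other 3, and Mmp8 had 2413 to 3790 against 119 to 162. Glycam1, a mucin-like ligand known from lymph node vessels, had the largest difference among tested genes, at 3.15 ± 0.65, with signals of 62 to 94 on the control arrays, 295 on PTEN-deletion replicate 1 and 2019 and 2234 on the other two, the arrays on which the T and NK list was highest. Tnn, which encodes tenascin N, differed by 2.40 ± 0.51, with signals of 144 to 413 against 697 to 2882. Ucp1, the uncoupling protein of brown fat, had signals of 103 and 134 on control replicates 3 and 1 and of 858 to 3255 on the other 4 arrays, and Adipoq, an adipocyte gene, 662 and 1749 against 3740 to 5554.

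The unfolded protein response and heat shock lists were lower on the PTEN-deletion arrays. Without control replicate 3 the median of the unfolded protein response was -0.332, against -0.492 with all arrays, and 20 of 20 genes were lower. The list means of the PTEN-deletion arrays, -0.441 to -0.548, then lay below both other controls (0.085 and -0.335), with control replicate 2 close to them. The difference that remained cannot come from control replicate 3. With 2 arrays against 3, it cannot be told apart from the spread between arrays (camera with an estimated correlation, adjusted p = 0.979). Folding genes of the endoplasmic reticulum outside the list had a median of -0.129 (20 genes, -0.148 to -0.065 with an array left out). The bar for a change beyond the list, set before these values were seen, lay inside that range. A change limited to the chosen genes therefore stays open. Heat shock factor targets outside the list had a median of -0.473 (13 genes, -0.646 to -0.38). A heat shock response higher in the control tissue would give this, through handling or through the genotype, which the design does not separate. These targets were read on the same arrays as the heat shock list, so they are not independent support. The spread between arrays stays open as well. Without control replicate 3 the immediate early and heat shock list had adjusted p = 0.979 (camera with an estimated correlation).

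Secretory airway genes were higher on PTEN-deletion replicates 1 and 3 and close to control on replicate 2. The goblet median was 0.757 with all arrays and 0.424 without control replicate 3, where the call ended (adjusted p = 0.0828) with fewer arrays and a smaller median. The list means of the arrays that remain overlapped, with PTEN-deletion replicate 2 at 0.269 and control replicate 1 at 0.373. The goblet difference that remained cannot come from control replicate 3. With the groups overlapping, it cannot be told apart from the spread between arrays (camera with an estimated correlation, adjusted p = 0.979). The club median was 0.444 with all arrays and 0.357 without that array, with 17 of 17 genes higher. The club means of the PTEN-deletion arrays, 0.248 to 0.839, then lay above both other controls (0.039 and 0.218), by a small margin for replicate 2. The club difference that remained cannot come from control replicate 3. With so few arrays and so small a margin, it cannot be told apart from the spread between arrays (camera with an estimated correlation, adjusted p = 0.979). More airway tissue in the PTEN-deletion samples would raise ciliated markers alike. The goblet median exceeded the ciliated median by 0.469 (0.317 to 0.709 with an array left out), but the difference of the list means was 0.251 on PTEN-deletion replicate 2 and 0.398 on control replicate 1, so airway share cannot be told apart either. The genotype also stays open, and it was not tested apart from the age and litter of the mice.

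Clock genes that peak from day to dusk, such as Per3 and Hlf, were higher on average relative to those that peak from night to dawn, such as Npas2. Of the former 7 of 10 were higher and of the latter 3 of 5 were lower, while Nr1d1 (-0.64), Ciart (-0.53), Per1 (-0.36), Clock (0.32) and Cry1 (0.25) went the other way. The difference between the classes was 0.709 on the log2 scale (exact permutation p = 0.3, 2-sided, where the smallest possible p is 0.1) and 0.398 without control replicate 3. The scores of the arrays that remain overlapped, with 0.269 and 0.352 on the controls and 0.117, 0.776 and 1.234 on the PTEN-deletion arrays. The difference that remained cannot come from control replicate 3. With the scores overlapping, it cannot be told apart from the spread between arrays. Time of day at collection may account for the difference between the classes. The 5 dusk-phase outputs outside the list had a median of 0.529, but the range with an array left out reached down to 0.09. That is below the bar of 0.1 set before these values were seen, so time of day cannot be told apart from the groups here.

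The 6 arrays can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 0 probe sets and 0 genes at adjusted p under 0.05, and the highest of the others was 6 probe sets and 11 genes. All 10 of 10 divisions reached a count of 0 in each case, a tally that was fixed in advance and tests nothing. At unadjusted p the real division gave 1445 genes (highest other 1085), the only 1 of the 10 with so many. For gene lists it gave 9 (highest other 11, with 4 of the 10 as large). The camera statistic of the unfolded protein response, as minus log10 p, was 9.5, again the highest of the 10, but 6.01 to 8.58 in the 3 divisions that put control replicates 1 and 3 together against control replicate 2. With array quality weights the real division gave 1136 genes and the highest other 4678, with 4 as large. The 3 divisions above it, at 3056 to 4678 genes, were those same 3. The estimate of the weights stopped with a convergence warning in 4 of the 10, which were the real division and these 3, so these counts are uncertain.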
